A study of Homo sapiens with 15 samples.

How the data were processed

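Transcript levels were measured in HEK293T cells, an established human embryonic kidney line, on Affymetrix U133 Plus 2.0 oligonucleotide arrays, with 1 array per sample and 15 arrays in all. Per the labels' protocols, total RNA was extracted with TRIzol, purified on RNeasy columns and checked on a Bioanalyzer. Per the submitters' processing notes, the authors computed MAS5 values in GCOS, the scanner's own software. Software versions, detection calls and the scaling target are not given in the sources used here.

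The deposited values are intensity values on a linear scale, 1 MAS5 signal per probe set and array, from 0 to 10743.9 with a median of 18.4. On every array the mean signal without the lowest and highest 2% of probe sets was 100, so the authors' values had already been scaled array by array, and no normalization between arrays was added. MAS5 subtracts mismatch probe signals, so dim probe sets are noisy and a fold change of a dim gene is imprecise.

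Probe sets were named through the platform annotation, which dates from 2016. Its Entrez identifiers matched 41043 probe sets of 1 gene to the GRCh38.p14 gene table, and no symbol differed between the tables. The symbols include EZHIP where the labels write CXorf67. They may therefore have been updated since 2016, and their match is no check of the annotation. The gene table also supplied chromosomes and the order of neighbouring genes, and no coordinates are given. In the table, 41091 probe sets had 1 gene symbol, 1801 had several and 11721 had none, besides 62 control probe sets. The 19775 genes with a probe set were each represented by the single-gene probe set of highest mean level over the 15 arrays. A gene was tested where its probe set lay above its own array's median on at least 3 of the 15 arrays, which left 12790 genes. Where other probe sets of a named gene went the opposite way, this is said beside the gene. Some named genes, among them TOX3, SSX1, MAGEA1, MAGEA6, HLA-C and HLA-F, were read by probe sets with the suffix _x_at. Such probe sets may also bind transcripts of related genes. Related members of a list may therefore share signal and need not be separate changes.

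Signals were analysed as log2(signal + 5), where the pseudocount of 5 is the rounded lower quartile of all deposited values. Fold changes are on this scale, which understates the change of dim genes. Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit, contrasts and eBayes with a mean-variance trend). All 15 arrays entered 1 fit with 5 groups and 10 residual degrees of freedom. P-values were adjusted by the Benjamini-Hochberg method over the 12790 genes in each of the 8 contrasts, with a threshold of 0.05, and all tests were two-sided. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

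There were 26 gene lists fixed in advance, of which 24 had at least 5 tested members. These were tested with limma's camera, a test of whether the members of a list changed more in one direction than the other genes, with a preset correlation between genes of 0.01. Camera p-values were adjusted over the 24 lists in each contrast. Each list was tested again with a correlation estimated from the arrays, and its members were also adjusted over the list alone. The filter dropped members of some lists. It kept, for example, 32 of 50 neuronal genes on the array, 91 of 149 Polycomb-target developmental regulators and 26 of 51 Polycomb-target signalling genes. Among glial, imprinted and cancer-testis genes it kept 9 of 24, 15 of 26 and 9 of 29. Members dim in the other groups entered only where raised arrays passed the filter. Medians and camera p-values of such lists therefore hold for tested members and can lean towards rises.

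The rule for named genes took, for each contrast, the 10 largest rises and the 10 largest falls among genes past the threshold whose arrays did not overlap between the sides. Where no gene passed, it took the 3 genes with the smallest p. EZHIP, EZH2, EED and SUZ12 were always included, as were up to 8 members of each list that passed in at least 1 contrast. For a list that passed with no member past the threshold, it added the 3 members with the smallest p. Unnamed loci and probe sets of several genes were not named. The groups, the 8 contrasts, the test, the filter, the pseudocount rule, the gene lists and this rule were chosen before the data were examined.

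The procedure was tested on data simulated for the contrast of full-length EZHIP with untransduced cells over the 12790 genes, with 200 genes changed. It recovered 72.8% of changes of 1 log2 unit and 96.5% of changes of 2, and 4.6% of its calls were false. The simulated noise was independent between genes and arrays, without shared structure by array number, and as many genes rose as fell. These rates need not hold for the real arrays. Arrays give no read depth, so their number limits the precision. With 3 arrays a side, the 95% interval of the median gene reached 0.357 log2 units to either side of its estimate. The exact permutation tests of 3 arrays against 3 cannot give a two-sided p below 0.1.

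The labels number the arrays of each group 1 to 3 and do not say whether a number marks a shared culture or day. They also do not say whether the 3 samples of a group came from separate cultures, so the p-values measure only the spread between these samples, which may be technical. Alternatives covered the pseudocount, the filter, normalization between arrays, the treatment of several probe sets, array weights, the variance trend, the arrays in the fit, the number as a block, and the omission of each array in turn.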

Results

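Expression profiles were obtained from HEK293T cells carrying lentiviral constructs for EZHIP, also called CXorf67, and from untransduced cells. The series title ties this protein to inhibition of PRC2, the complex that places the repressive H3K27 methyl mark, in posterior fossa ependymoma. The constructs encoded the full-length protein or its N-terminal, middle or C-terminal part, and each of the 5 groups held 3 arrays. Array medians lay between 15.4 and 21.5, the ratio of 3' to 5' GAPDH signal between 0.847 and 0.965, and the correlation between arrays between 0.958 and 0.981. The design asks which part of the protein changes transcription as the whole protein does.

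The EZHIP probe set was brightest with the full-length construct, at a signal of 17.6 ± 4.93 (SD, n = 3), against 2.27 ± 2.8 in untransduced cells. It read 4.7 ± 5.81 with the C-terminal part, 1.27 ± 0.59 with the middle part and 2.6 ± 0.46 with the N-terminal part. EZHIP was higher with the full-length protein than in the mean of the N-terminal and middle groups, with a log2 fold change of 1.69 ± 0.39 (SE, adjusted p = 0.0109). That call was lost without full-length array 3, at 1.56 and an adjusted p of 0.0728. Against untransduced cells its log2 fold change of 1.68 ± 0.44 had an adjusted p of 0.0529 and did not pass. It did without untransduced array 2 (1.97, adjusted p = 0.0452) and with the array number as a block (adjusted p = 0.0481). This EZHIP value was 2.80 with a pseudocount of 1 (adjusted p = 0.145) and 0.80 with the median of all values as pseudocount (adjusted p = 0.0245). The probe set was too dim for the filter and was tested in addition. Whether its target sequence lies within each construct is not known, so it does not show whether the truncated parts were expressed.

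The core subunits of PRC2 were bright and were not past the threshold in any of the 8 contrasts. EZH2, the catalytic subunit, read 665 ± 43.5 (SD, n = 3) with the full-length protein, 634 ± 51.3 with the C-terminal part and 636 ± 11.4 in untransduced cells. For EZH2 the log2 fold change against untransduced cells was 0.06 with a 95% interval of -0.16 to 0.28 for the full-length protein, and -0.01 with an interval of -0.23 to 0.21 for the C-terminal part. The log2 fold changes of the scaffold subunits EED and SUZ12 with the full-length protein were 0.13 (adjusted p = 0.685) and 0.21 (adjusted p = 0.411). Among the lists of PRC2 subunits, PRC1 subunits and cell cycle inhibitors, none passed camera in any contrast, and the smallest adjusted p-values were 0.0566, 0.219 and 0.184.

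**Figure D1:**
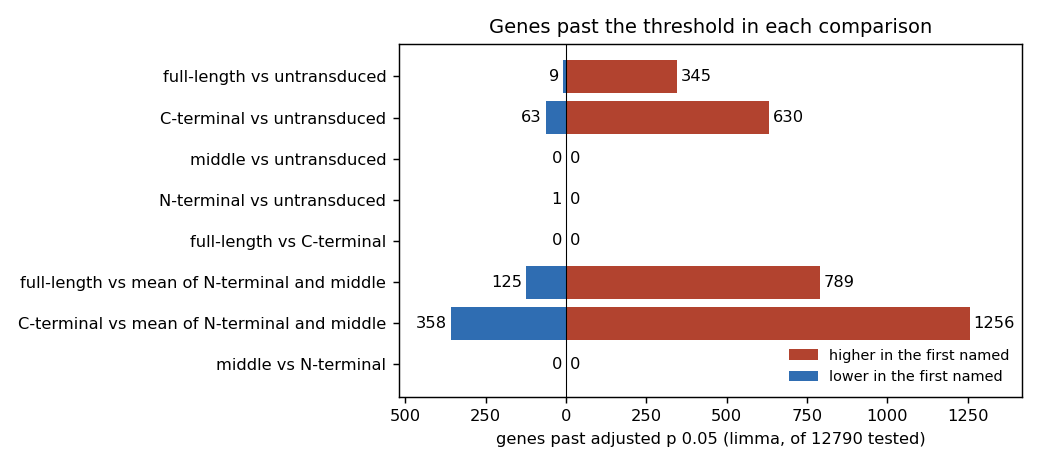
Number of genes past an adjusted p of 0.05 (limma, 12790 genes tested) in each of the 8 contrasts, on a horizontal axis that runs both ways from 0, with genes higher in the first named group to the right and genes lower to the left. The full-length protein and the C-terminal part against untransduced cells gave 354 and 693 genes, while the middle and N-terminal parts gave 0 and 1.

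Full-length EZHIP was first compared with untransduced cells, to see which transcripts respond to the intact protein. For genes that read below the pseudocount of 5 in untransduced cells the log2 fold change depends on the pseudocount. The increases were led by IL13RA2, a decoy receptor for interleukin 13, which read 303 ± 96.5 (SD, n = 3) against 0.83 ± 0.12 in untransduced cells, a log2 fold change of 5.67 ± 0.28 (SE, adjusted p = 1.38e-09). FGF13, an intracellular fibroblast growth factor homologue that binds sodium channels, read 772 ± 363 against 10.1 ± 5.14. TOX3, a transcription cofactor of neurons, read 277 ± 181 against 0.73 ± 0.38, and the cancer-testis antigen MAGEB2 rose 21.4-fold. Of the 12790 genes tested, 345 rose and 9 fell, and 245 of the rises were at least 2-fold.

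Other large rises were those of the membrane proteins ITM2A, MAL2 and FLRT2, with log2 fold changes of 4.91, 4.81 and 4.46. The long noncoding RNA TMEM132D-AS1 rose by 5.63, LRATD1 by 4.25 and the GABA receptor subunit GABRB2 by 4.01. The falls were smaller. TSC22D3, a glucocorticoid-induced leucine zipper protein, fell by 1.37 ± 0.23 (SE, adjusted p = 0.0021), from a signal of 1327 ± 324 (SD, n = 3) to 509.5 ± 125. WNT5A, a ligand of noncanonical Wnt signalling, fell by 1.06 ± 0.19 (SE, adjusted p = 0.00269), and SYBU, a syntaxin-binding linker of axonal transport, fell by 0.97 ± 0.19 (SE, adjusted p = 0.00634).

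Interferon-stimulated genes had a median log2 fold change of 0.25 with the full-length protein (camera adjusted p = 0.00248, or adjusted p = 0.332 with an estimated correlation). Of 26 tested members 4 were higher (6 adjusted over the list alone) and 22 did not pass. CMPK2, a mitochondrial nucleotide kinase, rose by 2.65 ± 0.26 (SE, adjusted p = 5.89e-06), and HERC5, the ligase that attaches ISG15 to proteins, by 0.89 ± 0.11 (SE, adjusted p = 0.000123). IFI27 rose by 1.27 (adjusted p = 0.022, up to 0.139 without full-length array 1 or 3 or untransduced array 3), but was also at 1.28 with the middle part (adjusted p = 0.819) and 1.20 with the N-terminal part (adjusted p = 0.728). Against the mean of these parts IFI27 was at 0.03 (adjusted p = 0.971). The interferon list did not pass without a filter or with the stricter one (adjusted p up to 0.127). Genes of MHC class I presentation had a median log2 fold change of 0.32 (camera adjusted p = 0.00248, or adjusted p = 0.241 with an estimated correlation), with 13 of 14 members above 0. No member of that list passed over all genes and 5 were higher adjusted over the list alone, led by HLA-C at 0.40 (adjusted p = 0.085) and the immunoproteasome subunit PSMB9 at 0.78 (adjusted p = 0.16).

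Cancer-testis and germline genes, which are normally silent outside the germline, had a median log2 fold change of 1.09 over 9 tested members (camera adjusted p = 6.29e-05, or adjusted p = 0.0857 with an estimated correlation). Only these 9 of 29 members on the array passed the filter. In this list 2 genes rose (5 adjusted over the list alone), MAGEB2 and MAGEC2, and 7 did not pass. MAGEC2 had a log2 fold change of 1.92 ± 0.42 (SE, adjusted p = 0.0164), which passed no longer without full-length array 1 or 3 or untransduced array 2 or 3 (adjusted p up to 0.0957). Serum and immediate-early response genes had a median of 0.50 over 23 members (camera adjusted p = 6.29e-05, or adjusted p = 0.272 with an estimated correlation). There 3 genes rose (9 adjusted over the list alone), among them SPRY2, a feedback inhibitor of receptor tyrosine kinase signalling, by 0.96 ± 0.14 (SE, adjusted p = 0.00039).

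Fibroblast and mesenchymal markers had a median log2 fold change of 0.46, with 1 of 13 members higher (5 adjusted over the list alone) and a camera adjusted p = 0.00248 (adjusted p = 0.332 with an estimated correlation). Epithelial and kidney markers had a median of 0.37, with 2 of 8 members higher (3 adjusted over the list alone) and a camera adjusted p = 0.0121 (adjusted p = 0.241 with an estimated correlation). The epithelial call ended when no filter was used, with an adjusted p of 0.679.

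Polycomb-target signalling genes had 5 of 26 members higher and 1 lower (6 and 1 adjusted over the list alone), with a median log2 fold change of 0.26 (camera adjusted p = 0.0217, or adjusted p = 0.363 with an estimated correlation). BMP2, a bone morphogenetic protein, rose by 3.35 ± 0.58 (SE, adjusted p = 0.00253), the Wnt ligand WNT11 by 2.10 ± 0.38 (SE, adjusted p = 0.00333) and the Wnt antagonist DKK1 by 1.44 ± 0.19 (SE, adjusted p = 0.000151), while WNT5A was the member that fell. Polycomb-target developmental regulators had 5 of 91 members higher (9 adjusted over the list alone, with 1 lower) and a median of 0.16 (camera adjusted p = 0.0334, or adjusted p = 0.363 with an estimated correlation). Their members past the threshold included the neuronal transcription factor BHLHE22 at 2.49 ± 0.34 (SE, adjusted p = 0.00022) and the homeobox gene MSX2 at 1.34 ± 0.23 (SE, adjusted p = 0.00251). The signalling list lost its call without untransduced array 1 or full-length array 3 (adjusted p up to 0.101), and the developmental list without untransduced array 1 or 3 or full-length array 3 (up to 0.305). Both also lost it without a filter and after quantile normalization (up to 0.728 and 0.169).

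Neuronal genes had a median log2 fold change of 0.26 over 32 members with 0 past the threshold by limma (camera adjusted p = 0.0158, or adjusted p = 0.241 with an estimated correlation). That call ended without full-length array 3 (adjusted p = 0.0707). HOX genes, classical Polycomb targets, went the other way as a list, with a median of -0.13 and 0 of 25 members past the threshold by limma (camera adjusted p = 0.0158, or adjusted p = 0.464 with an estimated correlation). The HOX call ended without untransduced array 1 (adjusted p = 0.0923). HOX genes did not pass against the mean of the N-terminal and middle parts, and they also passed downward with the N-terminal part against untransduced cells. The list of H3K27 demethylases and DNA methylation had a median of -0.10 (camera adjusted p = 0.0158, or adjusted p = 0.332 with an estimated correlation), lost without untransduced array 2 or full-length array 3 (adjusted p up to 0.238). The last 3 of the 14 lists past the threshold each held 1 risen gene. These were the p53 target PLK2, the glial glutamate transporter SLC1A2 and the imprinted gene PHLDA2, at log2 fold changes of 2.24, 2.28 and 2.27. Their lists gave camera adjusted p-values of 0.0107, 0.033 and 0.0334, and an adjusted p of 0.582, 0.241 and 0.363 with an estimated correlation. The p53 call ended without full-length array 1 (adjusted p = 0.365), the glial call without full-length array 3 or untransduced array 2 (up to 0.0732), and the imprinted call without full-length array 1 or untransduced array 1 or 3 (up to 0.123). The stricter filter also ended the neuronal, HOX, demethylase and imprinted calls, and the lack of a filter ended the glial and imprinted calls (up to 0.679).

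The count of 354 changed genes with the full-length protein was 210 without full-length array 3, 214 without untransduced array 3, 138 with the stricter filter and 737 (644 higher, 93 lower) with array weights. With the array number as a block it was 493 (444 higher, 49 lower). Of the 44 named genes past the threshold, 26 kept it whichever of the 6 arrays was left out, and 18 did not, with an adjusted p of up to 0.256.

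**Figure D2:**
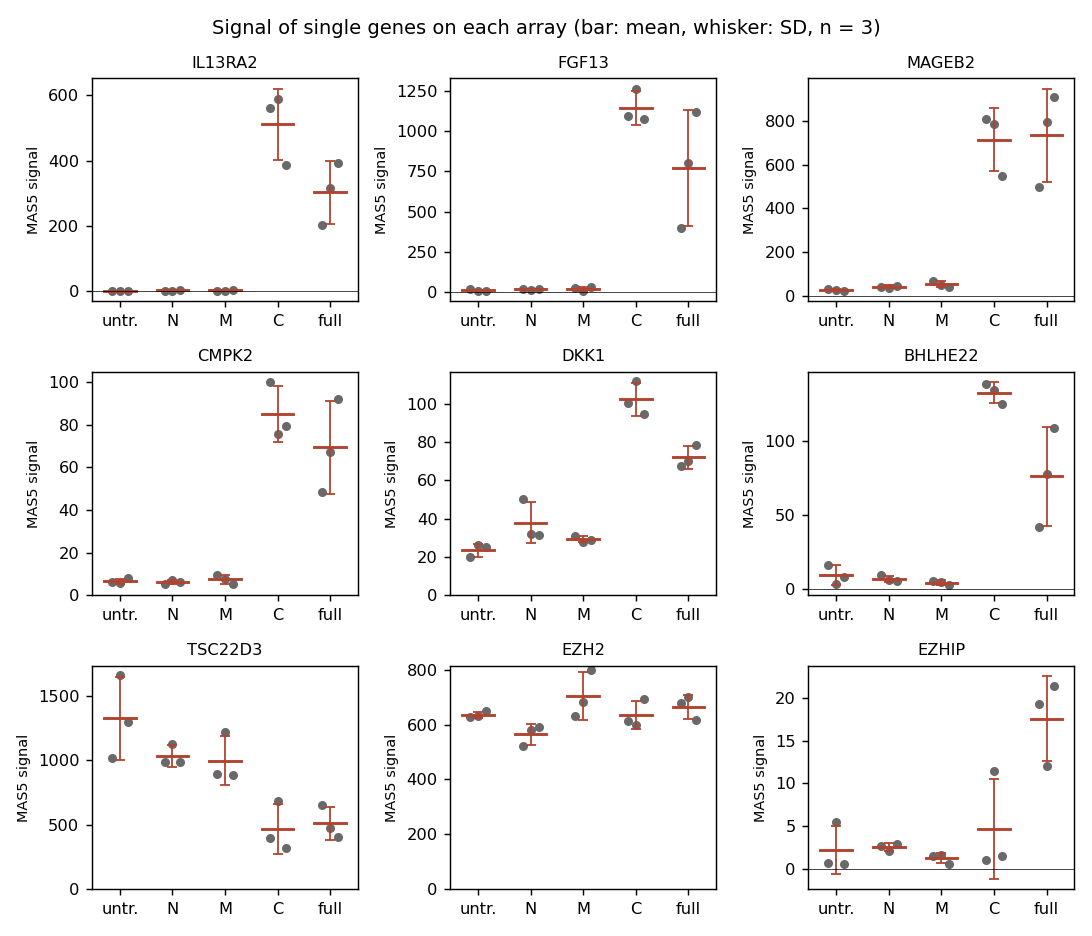
MAS5 signal (linear scale, vertical axes that include 0) of 9 genes on each of the 15 arrays, by group (untransduced, N-terminal part, middle part, C-terminal part, full-length). Points are arrays, bars group means and whiskers 1 SD (n = 3), and IL13RA2 averaged 512 with the C-terminal part and 303 with the full-length protein against 0.83 in untransduced cells, while EZH2 lay between group means of 565 and 704.

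The C-terminal part was compared with untransduced cells in the same way. It raised the genes that led the full-length comparison, with IL13RA2 at 512 ± 109 (SD, n = 3), a log2 fold change of 6.45 ± 0.28 (SE, adjusted p = 2.6e-10), and FGF13 at 1145 ± 105 (SD, n = 3), a log2 fold change of 6.30. TMEM132D-AS1 rose by 6.58. The embryonic globin HBE1 rose from 4.27 ± 2.53 (SD, n = 3) to 234 ± 64.4, and TCEAL7, an X-linked relative of a transcription elongation factor, from 7.83 ± 1.71 (SD, n = 3) to 380 ± 220. Among the falls, TSC22D3 fell by 1.55 ± 0.23 (SE, adjusted p = 4e-04), SYBU by 1.15 ± 0.19 (SE, adjusted p = 0.000877), WNT5A by 1.04 ± 0.19 (SE, adjusted p = 0.00184) and the bZIP transcription factor MAF by 0.99 ± 0.14 (SE, adjusted p = 0.00015). In all 630 genes rose and 63 fell, and with every array set to the same median 539 rose and 139 fell.

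Cancer-testis and germline genes had a median log2 fold change of 1.82 with the C-terminal part, with 6 of 9 members higher and 8 adjusted over the list alone (camera adjusted p = 3.23e-08). This was the list whose call held with an estimated correlation, at an adjusted p = 0.0122. Of 29 members on the array only these 9 passed the filter, and members that stayed dim did not enter. The values therefore hold for the tested members and not for the whole list. MAGEB2 rose by 4.41 ± 0.22 (SE, adjusted p = 1.29e-09) and MAGEC2 by 2.14 ± 0.42 (SE, adjusted p = 0.00427). The others past the threshold were SSX1, MAGEC1, MAGEA1 and PIWIL1, a piRNA-binding protein of the germline, at log2 fold changes of 1.79 to 2.00, and each passed no longer without C-terminal array 1. MAGEC1 and PIWIL1 were also lost without untransduced array 3, MAGEA1 and PIWIL1 without C-terminal array 2, and MAGEA1 without untransduced array 1 or 2 (adjusted p up to 0.115). The probe sets of SSX1 and MAGEA1 carried the suffix _x_at, so their signals may include related genes.

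The p53 targets had a median log2 fold change of 0.74 with the C-terminal part (camera adjusted p = 8.77e-07, or adjusted p = 0.504 with an estimated correlation). Of their 19 members 6 were higher (15 adjusted over the list alone) and 13 did not pass. SESN1, a stress-induced inhibitor of growth signalling, rose by 1.16 ± 0.19 (SE, adjusted p = 0.000997) and PLK2 by 2.27 ± 0.41 (SE, adjusted p = 0.00209). Genes of the unfolded protein response and integrated stress had 4 of 30 members lower (9 adjusted over the list alone), 26 not past the threshold, a median of -0.16 and a camera adjusted p = 0.000101 (adjusted p = 0.299 with an estimated correlation). Those 4 were the amino acid genes PSAT1 (log2 fold change -0.77), SLC7A11 (-1.21) and ASNS (-0.92) and the mTORC1 inhibitor DDIT4 (-1.46), and none of them passed without C-terminal array 1. ASNS was also lost without untransduced array 2, and DDIT4 without untransduced array 2 or 3 or C-terminal array 3 (adjusted p up to 0.153). Cholesterol synthesis genes had a median of -0.33, with 1 of 19 members lower (6 adjusted over the list alone, camera adjusted p = 0.00105, or adjusted p = 0.504 with an estimated correlation).

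Neuronal genes had a median log2 fold change of 0.45 with the C-terminal part, with 4 of 32 members higher (12 adjusted over the list alone, with 1 lower) and a camera adjusted p = 0.00854 (adjusted p = 0.212 with an estimated correlation). The dendritic microtubule protein MAP2 rose by 1.72 ± 0.34 (SE, adjusted p = 0.00374). The neuronal call did not hold with the stricter filter (adjusted p = 0.212). MHC class I genes had a median of 0.32, with 2 of 14 members higher (2 adjusted over the list alone, camera adjusted p = 0.00854, or adjusted p = 0.274 with an estimated correlation). In the interferon list 5 of 26 members rose (8 adjusted over the list alone, camera adjusted p = 0.0126, or adjusted p = 0.504 with an estimated correlation), among them CMPK2 by 2.96 and HERC5 by 0.85. Against the mean of the N-terminal and middle parts the interferon list missed the threshold (median 0.25, camera adjusted p = 0.107), with 5 members higher (5 adjusted over the list alone). The interferon call against untransduced cells ended without C-terminal array 2 (adjusted p = 0.0986) and with no filter or the stricter one (up to 0.388). Glial genes (camera adjusted p = 0.0247, or adjusted p = 0.212 with an estimated correlation) and fibroblast markers (0.0136, or adjusted p = 0.504 with an estimated correlation) also lost the call without that array, at 0.0734 and 0.108. The serum response list passed with an adjusted p = 0.016 (adjusted p = 0.504 with an estimated correlation) but not without C-terminal array 2 or untransduced array 1 (up to 0.0988).

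The Polycomb-target lists did not pass for the C-terminal part, with camera adjusted p-values of 0.138 and 0.134. Of the 91 developmental regulators 8 rose (13 adjusted over the list alone, with 4 lower), and of the 26 signalling genes 5 rose and 1 fell (6 and 2 adjusted over the list alone). Their members past the threshold included BHLHE22 at 3.34 ± 0.34 (SE, adjusted p = 5.29e-06), FOXQ1, a forkhead factor, at 1.71 ± 0.24 (SE, adjusted p = 2e-04), DKK1 at 1.91 ± 0.19 (SE, adjusted p = 3.43e-06), BMP2 at 3.42 ± 0.58 (SE, adjusted p = 0.00118) and the Wnt antagonist SFRP1 at 1.81 ± 0.34 (SE, adjusted p = 0.0028). ACTA2, smooth muscle actin, rose by 2.54 ± 0.47 (SE, adjusted p = 0.00232).

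The count of 693 for the C-terminal part was 391 without C-terminal array 1, 427 without C-terminal array 2, 388 without untransduced array 3, 306 with the stricter filter and 2283 (1498 higher, 785 lower) with array weights. With the array number as a block it was 1119 (885 higher, 234 lower). Of the 65 named genes past the threshold, 35 kept it whichever array was left out, and 30 did not, with an adjusted p of up to 0.255.

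The responses to the full-length protein and to the C-terminal part were then set side by side. Of the 345 genes that rose with the full-length protein, 323 (93.6%) also rose with the C-terminal part, 7 fell with both and 0 went opposite ways by limma. Independent lists of these sizes would share 17 rises. Across genes, which are not independent replicates, the log2 fold changes correlated with r = 0.904 and rho = 0.775 against an r of 0.502 for unchanged groups simulated on the same controls, and their covariance was 0.181 against a simulated 0.0266. The 3 untransduced arrays entered both comparisons and cannot be split, so part of the overlap beyond 17 may come from shared controls. Between the full-length protein against the N-terminal part and the C-terminal part against the middle part, which share no array, r was 0.792 (simulated 0.001) and the covariance 0.169 (simulated 1e-04). In that pair 394 genes rose in both against 37.6 for independent lists of 498 and 966.

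Over the 323 genes, which include IL13RA2, FGF13, TOX3 and MAGEB2, the mean log2 level lay 1.69 above untransduced cells with the full-length protein and 2.00 with the C-terminal part (exact permutation p = 0.1 each, the smallest possible). It lay 0.08 above with the middle part and 0.12 with the N-terminal part (exact permutation p = 0.3 each). The genes had been chosen by their rises with the full-length protein and the C-terminal part over these same untransduced arrays. The exact permutation p-values of those constructs were therefore fixed by the choice and lend no support. Those of the middle and N-terminal parts also rest on untransduced arrays that the choice favoured as low. In untransduced cells 51.1% of the 323 genes lay below the array median, against 9.4% of all tested genes. The filter had kept such dim genes only where at least 3 of the 15 arrays read above it. The count of 323 was 198 without full-length array 3, 202 without untransduced array 3 and 126 with the stricter filter.

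**Figure D3:**
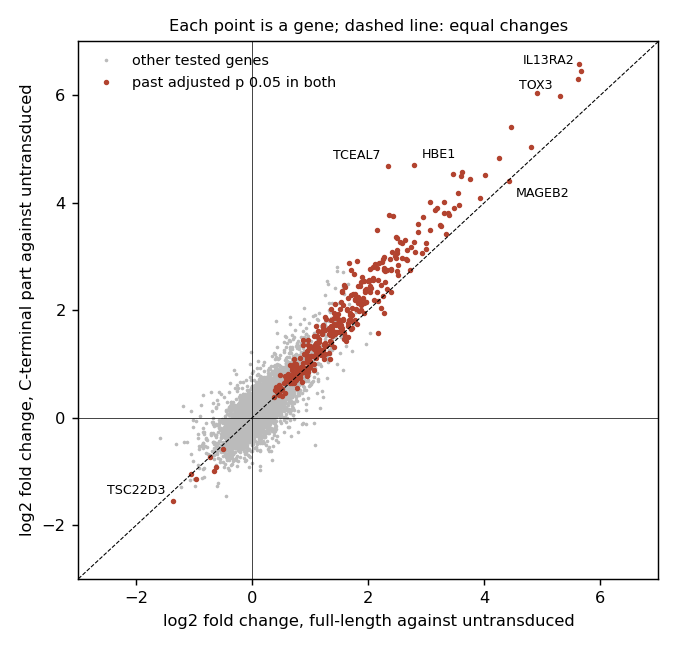
Log2 fold change of each of the 12790 genes against untransduced cells, with the full-length protein on the horizontal axis and the C-terminal part on the vertical axis. Red points are genes past an adjusted p of 0.05 in both, grey points the others, and the dashed line marks equal changes; 323 genes rose and 7 fell in both.

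The middle part was compared with untransduced cells to see whether it changes expression by itself. By limma 0 genes passed the threshold, with 539 at an unadjusted p under 0.05 against 640 expected by chance. The 3 genes with the smallest p were POLL, a repair DNA polymerase, with a log2 fold change of -1.13, CCNG2, cyclin G2, at -0.56, and the glycosyltransferase gene RXYLT1 at 0.61. Each had an adjusted p of 0.819. Other probe sets of CCNG2 went the opposite way in 2 of 3 cases. Ribosomal protein genes had a median log2 fold change of 0.09 over 40 members, with 0 past the threshold by limma over all genes or adjusted over the list alone (camera adjusted p = 0.000277, or adjusted p = 0.677 with an estimated correlation). That list gave 0.8 after quantile normalization. Its smallest p-values belonged to RPS28 (log2 fold change 0.17), RPS3 (0.13) and RPL38 (0.12), and RPS28, whose 2 other probe sets went the opposite way, turned to -0.05 as the mean of its probe sets.

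Mitosis and DNA replication genes had a median of 0.08 with the middle part (camera adjusted p = 0.0042, or adjusted p = 0.677 with an estimated correlation). It was led by the kinesin KIF20A at 0.26 and cyclin E, CCNE1, at 0.25 (adjusted p = 0.988 each). The unfolded protein response list had a median of -0.10 (camera adjusted p = 0.0325, or adjusted p = 0.677 with an estimated correlation), led by VLDLR at -0.75 and STC2 at -0.57 (adjusted p = 0.988 each). None of these 3 calls held without each array in turn. The ribosomal call ended without middle array 1 or untransduced array 3 (adjusted p up to 0.199), and the mitosis call without middle array 3 or untransduced array 2 (up to 0.152). The stress call ended without middle array 1 or 2 or untransduced array 2 or 3 (up to 0.24). Quantile normalization also ended the mitosis call (0.0866), and the mean of probe sets the stress call (0.0776). With array weights 38 genes passed (10 higher, 28 lower).

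For the N-terminal part against untransduced cells, 1 gene passed. CCNG2, a cyclin that restrains the cell cycle, fell by 0.97 ± 0.12 (SE, adjusted p = 0.00309), from 415 ± 24.5 (SD, n = 3) to 210 ± 12.3. As the mean of its probe sets, CCNG2 had a log2 fold change of -0.40 and an adjusted p of 0.937, so 0 genes passed by limma, and with array weights 8 passed. At an unadjusted p under 0.05 there were 744 genes, against 640 expected by chance.

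Ribosomal protein genes had a median log2 fold change of 0.16 with the N-terminal part, with 38 of 40 members above 0 and 0 past the threshold by limma (camera adjusted p = 2.55e-10, or adjusted p = 0.693 with an estimated correlation). After quantile normalization that median was 0, and the call ended (adjusted p = 0.879). Heat shock genes had a median of 0.22 (camera adjusted p = 0.000131, or adjusted p = 0.466 with an estimated correlation), with 0 of 10 members higher by limma over all genes and 4 adjusted over the list alone. The chaperones HSP90AB1, HSP90AA1 and HSPD1 had log2 fold changes of 0.25, 0.18 and 0.20 (adjusted p = 0.728, 0.729 and 0.767), with 1 of 3 other probe sets of HSPD1 going the opposite way. The p53 targets had a median of 0.35 with 19 of 19 members above 0, led by BAX, a mediator of apoptosis, at 0.51 and TP53I3 at 0.76 (adjusted p = 0.728 each). Their camera adjusted p = 6.66e-05 (adjusted p = 0.693 with an estimated correlation) rested on N-terminal array 1, without which the adjusted p was 0.548.

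The other 5 lists past the threshold for the N-terminal part lost the call without 1 array, and all 5 lost it with no filter. Hypoxia and glycolysis genes (median 0.11, camera adjusted p = 0.0183, or adjusted p = 0.693 with an estimated correlation) and serum response genes (0.15, 0.0301, or adjusted p = 0.723 with an estimated correlation) lost it without N-terminal array 1 or untransduced array 1, at up to 0.124 and 0.289. Housekeeping genes (0.10, 0.0183, or adjusted p = 0.693 with an estimated correlation, turning to -0.02 after quantile normalization) lost it without N-terminal array 2 or 3 or untransduced array 3, at up to 0.0684. HOX genes (-0.06, 0.0476, or adjusted p = 0.74 with an estimated correlation) lost it without N-terminal array 1 or 2 or untransduced array 1, at up to 0.509. Stress response genes (-0.12, 0.0476, or adjusted p = 0.723 with an estimated correlation) lost it without N-terminal array 1 or 2 or untransduced array 2 or 3, at up to 0.548.

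**Figure D4:**
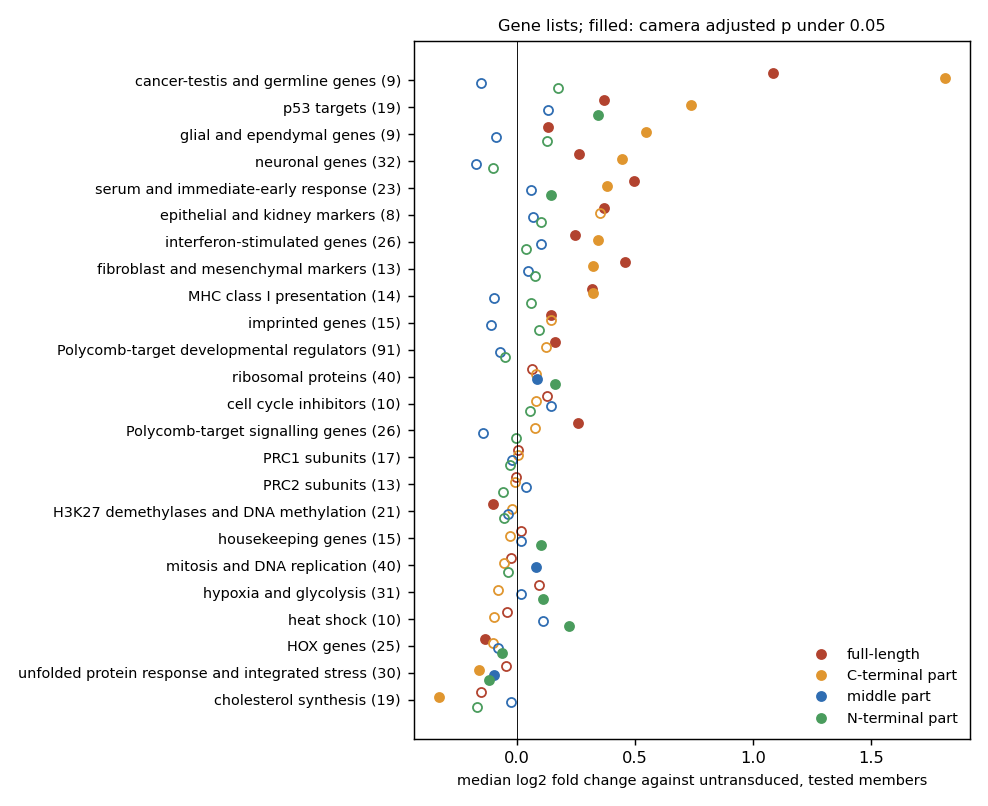
Median log2 fold change against untransduced cells (horizontal axis) of the tested members of each of 24 gene lists (vertical axis, number of members in brackets) for the 4 constructs, with filled circles where camera passed an adjusted p of 0.05. Cancer-testis and germline genes stood at 1.82 with the C-terminal part and 1.09 with the full-length protein, while the ribosomal and housekeeping medians of the N-terminal part moved to 0 and -0.02 after quantile normalization.

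The full-length protein was compared directly with the C-terminal part, to see whether the rest of the protein adds to or takes from the response. By limma 0 genes passed, with 372 at an unadjusted p under 0.05 against 640 expected by chance. A gene of median precision could differ by up to 0.357 log2 units in either direction within its 95% interval. The smallest p-values were those of HBE1, with a log2 fold change of -1.90 and an interval of -2.59 to -1.21 (adjusted p = 0.192), CCNG2 at 0.66 (adjusted p = 0.192, with 2 of 3 other probe sets going the opposite way) and the calcium-binding protein CALB1 at -1.42 (adjusted p = 1). HBE1 read 57.8 ± 8.31 (SD, n = 3) with the full-length protein and 234 ± 64.4 with the C-terminal part. Over the 323 genes that rose with both, 280 (86.7%) were higher with the C-terminal part, and the mean difference was -0.31 (exact permutation p = 0.2), or -0.17 without full-length array 1.

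Between these groups 6 lists passed camera, without any member past the threshold over all genes. Cancer-testis and germline genes were lower with the full-length protein, at a median of -0.68 (camera adjusted p = 5.2e-05, or adjusted p = 0.0888 with an estimated correlation). Of their 9 members 1 was lower adjusted over the list alone, with MAGEA1, MAGEA6 and SSX1 at -1.39, -0.88 and -0.81 (adjusted p = 1 each). The p53 targets were lower at a median of -0.45 (camera adjusted p = 8.85e-07, or adjusted p = 0.609 with an estimated correlation). Of their 19 members 1 was lower adjusted over the list alone, with SESN1, BAX and XPC at -0.68, -0.47 and -0.43 (adjusted p = 1 each). Hypoxia and glycolysis genes were higher at a median of 0.15 (camera adjusted p = 4.33e-06, or adjusted p = 0.0888 with an estimated correlation), with the aldolase ALDOC at 0.53 and the mitophagy gene BNIP3 at 0.35 (adjusted p = 1 each). Unfolded protein response and stress genes were higher at a median of 0.17 (camera adjusted p = 1.03e-05, or adjusted p = 0.338 with an estimated correlation), with CHAC1 at 0.83 and DDIT4 at 1.00 (adjusted p = 1 each). Cholesterol synthesis genes stood at 0.17 (camera adjusted p = 0.000432, or adjusted p = 0.609 with an estimated correlation), with the call lost without C-terminal array 1 or full-length array 2 (up to 0.758). Serum response genes stood at 0.11 (camera adjusted p = 0.0255, or adjusted p = 0.674 with an estimated correlation). Without C-terminal array 1 or 3 or full-length array 1 the call was lost (up to 0.952), with a median down to -0.01. It was also lost with no filter or the stricter one (up to 0.281).

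The full-length protein was also compared with the mean of the N-terminal and middle parts, which were transduced as well. IL13RA2, TOX3 and FGF13 were again among the largest rises, at log2 fold changes of 5.52 ± 0.24 (SE, adjusted p = 3.17e-10), 5.14 ± 0.38 (SE, adjusted p = 1.37e-07) and 4.99 ± 0.32 (SE, adjusted p = 2.64e-08), and TMEM132D-AS1 rose by 5.05. CHRDL1, a secreted antagonist of bone morphogenetic proteins, rose by 3.78 ± 0.27 (SE, adjusted p = 7.16e-08). TSC22D3 fell by 1.01 ± 0.20 (SE, adjusted p = 0.00491), and COX20, an assembly factor of cytochrome c oxidase, fell by 0.95 ± 0.16 (SE, adjusted p = 0.00126). Of all genes 789 rose and 125 fell, and with every array set to the same median 624 rose and 317 fell.

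Neuronal genes had 10 of 32 members higher in this contrast (13 adjusted over the list alone), with a median of 0.32 and a camera adjusted p = 0.0019 (adjusted p = 0.12 with an estimated correlation). They included the RNA-binding proteins ELAVL2 at 0.58 and RBFOX3 at 1.18 and the growth cone protein GAP43 at 0.92, which were lost without full-length array 3 (adjusted p = 0.108, 0.122 and 0.0573). Cancer-testis genes had a median of 0.86, with 4 of 9 members higher (6 adjusted over the list alone, camera adjusted p = 4e-04, or adjusted p = 0.12 with an estimated correlation). Polycomb-target signalling genes had 7 of 26 higher and 1 lower (8 and 1 adjusted over the list alone), a median of 0.23 and a camera adjusted p = 0.00722 (adjusted p = 0.31 with an estimated correlation), and the call ended with the stricter filter (adjusted p = 0.111). WNT11, SFRP1, DKK1 and BMP2 rose by 2.44, 2.10, 1.02 and 2.93, and ALDH1A3, an enzyme of retinoic acid synthesis, by 1.18. Polycomb-target developmental regulators had 11 of 91 higher and 1 lower (23 and 2 adjusted over the list alone), a median of 0.18 and a camera adjusted p = 0.00722 (adjusted p = 0.31 with an estimated correlation). That call ended without full-length array 3 (adjusted p = 0.0758) and after quantile normalization (0.0712). The calls of BHLHE22 at 2.83 and SOX8, a neural crest factor, at 1.25 held without any 1 array.

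MHC class I genes had 4 of 14 members higher (7 adjusted over the list alone), a median of 0.38 and a camera adjusted p = 0.00722 (adjusted p = 0.247 with an estimated correlation), with HLA-F at 0.47 ± 0.11 (SE, adjusted p = 0.0109). Fibroblast markers had 4 of 13 higher (6 adjusted over the list alone), a median of 0.55 and a camera adjusted p = 0.00852 (adjusted p = 0.444 with an estimated correlation). Imprinted genes had 1 of 15 higher (3 adjusted over the list alone), PHLDA2 at 1.76, a median of 0.28 and a camera adjusted p = 0.00855 (adjusted p = 0.31 with an estimated correlation), not kept when no filter was used (0.0641). Heat shock genes had a median of -0.22 with 0 of 10 lower by limma over all genes and 3 adjusted over the list alone (camera adjusted p = 0.00786, or adjusted p = 0.31 with an estimated correlation), and the call was not kept after quantile normalization (0.126). Interferon-stimulated genes missed the threshold here (median 0.21, camera adjusted p = 0.0525), with 3 of 26 members higher (4 adjusted over the list alone), among them CMPK2 by 2.62 and HERC5 by 0.59. CDH1, the epithelial cadherin, rose by 1.54 ± 0.22 (SE, adjusted p = 0.000234).

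Of the 12 lists past the threshold the remaining 4 lost the call without 1 array. Serum response genes (median 0.41, camera adjusted p = 0.00852, or adjusted p = 0.477 with an estimated correlation) lost it without full-length array 1 (0.297), and glial genes (0.49, 0.0269, or adjusted p = 0.224 with an estimated correlation) without full-length array 3 (0.0618). Ribosomal protein genes (-0.06, 0.00722, or adjusted p = 0.762 with an estimated correlation) lost it without middle array 1 or full-length array 2 (up to 0.131), and mitosis genes (-0.06, 0.0243, or adjusted p = 0.641 with an estimated correlation, turning above 0 after quantile normalization) without full-length array 1, N-terminal array 2 or 3 or middle array 3 (up to 0.112). The count of 914 was 471 without full-length array 3, 433 with the stricter filter and 2066 (1427 higher, 639 lower) with array weights, and of 69 named genes past the threshold 33 kept it whichever of the 9 arrays was left out.

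The C-terminal part against the mean of the N-terminal and middle parts gave the most calls. IL13RA2 had a log2 fold change of 6.29 ± 0.24 (SE, adjusted p = 3.5e-11), ITM2A of 5.99 and the mesenchymal cadherin CDH11 of 4.61. ITM2A read 461 with the C-terminal part against 2.43 and 1.67 with the middle and N-terminal parts, and CDH11 read 193 against 2.93 and 3.77. Among the falls, the mitochondrially encoded ND6 fell by 1.28 ± 0.19 (SE, adjusted p = 0.000251), BCAN, a brain proteoglycan, by 1.27 ± 0.24 (SE, adjusted p = 0.00145) and the ferritin light chain FTL by 0.87 ± 0.12 (SE, adjusted p = 0.000129). In all 1256 genes rose and 358 fell. With every array set to the same median, which moved the median of all genes by -0.11, 992 rose and 1043 fell, and after quantile normalization 1110 rose and 358 fell.

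Cancer-testis and germline genes had a median of 1.76, with 8 of 9 members higher (8 adjusted over the list alone), a camera adjusted p = 4.5e-07 and an adjusted p = 0.021 with an estimated correlation. MAGEB2, SSX1, MAGEA1 and PIWIL1 rose by 3.72, 2.10, 2.19 and 2.23, and PRAME, a cancer-testis antigen with a higher starting level, by 0.55. Neuronal genes had 15 of 32 members higher (16 adjusted over the list alone, with 1 lower), a median of 0.47 and a camera adjusted p = 0.000968 (adjusted p = 0.0951 with an estimated correlation). In both lists only members past the filter entered, 9 of 29 cancer-testis and 32 of 50 neuronal genes on the array. STMN2, a regulator of axonal microtubules, rose by 3.18 ± 0.54 (SE, adjusted p = 0.000689), the RNA-binding protein ELAVL4 by 1.72 ± 0.32 (SE, adjusted p = 0.00137) and the adhesion molecule NCAM1 by 0.76 ± 0.17 (SE, adjusted p = 0.00659).

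The p53 targets had 8 of 19 members higher (12 adjusted over the list alone), a median of 0.51 and a camera adjusted p = 0.0016 (adjusted p = 0.513 with an estimated correlation). Heat shock genes had 2 of 10 members lower (6 adjusted over the list alone), HSPE1 at -0.42 and HSP90AB1 at -0.27 (both lost without C-terminal array 1 or 2, adjusted p up to 0.113), a median of -0.26 and a camera adjusted p = 0.0012 (adjusted p = 0.206 with an estimated correlation). Cholesterol synthesis genes had 2 of 19 lower and 1 higher (4 and 1 adjusted over the list alone), a median of -0.22 and a camera adjusted p = 0.00873 (adjusted p = 0.513 with an estimated correlation). MHC class I genes had 2 of 14 higher (7 adjusted over the list alone, with 1 lower), HLA-F at 0.68 and HLA-C at 0.50, a median of 0.30 and a camera adjusted p = 0.0169 (adjusted p = 0.285 with an estimated correlation). Imprinted genes had 3 of 15 higher (6 adjusted over the list alone), a median of 0.29 and a camera adjusted p = 0.0317 (adjusted p = 0.486 with an estimated correlation), lost with the mean of probe sets (0.052).

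Polycomb-target developmental regulators had 20 of 91 members higher and 1 lower (25 and 4 adjusted over the list alone), a median of 0.12 and a camera adjusted p = 0.0359 (adjusted p = 0.486 with an estimated correlation). Signalling genes had 7 of 26 higher and 1 lower (8 and 1 adjusted over the list alone), a median of 0.29 and a camera adjusted p = 0.038 (adjusted p = 0.486 with an estimated correlation). BHLHE22 rose by 3.68, PAX7, a neural crest and muscle factor, by 1.59, LHX2, a forebrain factor, by 1.32 and RUNX2, a bone factor, by 1.19, and these kept the call whichever array was left out. The developmental list lost its call without N-terminal array 1 or C-terminal array 3 (adjusted p up to 0.0697), and the signalling list without N-terminal array 1, C-terminal array 2 or middle array 3 (up to 0.16). With no filter and after quantile normalization both calls also ended (up to 0.298 and 0.254).

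The other 6 of the 15 lists past the threshold were each lost without at least 1 array. Stress response genes (camera adjusted p = 0.022, or adjusted p = 0.486 with an estimated correlation) and glial genes (0.0317, or adjusted p = 0.206 with an estimated correlation) were lost without C-terminal array 3, at 0.0522 and 0.0546. Ribosomal protein genes (0.0317, or adjusted p = 0.725 with an estimated correlation, median -0.05, turning to 0.01 after quantile normalization) were lost without N-terminal array 1, middle array 1 or C-terminal array 3, at up to 0.571. Fibroblast markers (0.0359, or adjusted p = 0.513 with an estimated correlation) were lost without C-terminal array 2, N-terminal array 3 or middle array 3, at up to 0.16. Housekeeping genes (0.0359, or adjusted p = 0.486 with an estimated correlation) were lost without C-terminal array 1 or 3 or N-terminal array 3, at up to 0.0905. Mitosis genes (0.0429, or adjusted p = 0.629 with an estimated correlation, median -0.05, turning to 0.03 after quantile normalization) were lost without C-terminal array 1 or 2, N-terminal array 2 or 3 or middle array 3, at up to 0.413. The stricter filter and quantile normalization each ended the stress, ribosomal, housekeeping and mitosis calls, quantile normalization the glial call and the mean of probe sets the fibroblast call. The count of 1614 was 755 without C-terminal array 1, 872 without C-terminal array 2, 934 with the stricter filter and 3761 (2311 higher, 1450 lower) with array weights, and of 100 named genes past the threshold 60 kept it whichever of the 9 arrays was left out.

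Between the middle and the N-terminal part, 0 genes passed by limma, with 459 at an unadjusted p under 0.05 against 640 expected by chance. The smallest p-values were those of CCNF, cyclin F, with a log2 fold change of 0.55, the translation factor EIF2D at -0.51 and GPSM2, an organiser of the mitotic spindle, at 0.54 (adjusted p = 1 each), though another probe set of GPSM2 went the opposite way. Mitosis and DNA replication genes were higher with the middle part by a median of 0.17, with 29 of 40 members above 0 and 0 past the threshold by limma or adjusted over the list alone (camera adjusted p = 2.7e-07, or adjusted p = 0.653 with an estimated correlation). The kinetochore protein NDC80, the kinesin KIF11 and the centromere protein CENPF had log2 fold changes of 0.45, 0.39 and 0.34 (adjusted p = 1 each). The p53 targets were lower by a median of -0.25 (camera adjusted p = 0.00331, or adjusted p = 0.655 with an estimated correlation), with BAX at -0.55.

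All 4 lists past the threshold between these parts lost the call without N-terminal array 1. For mitosis genes the adjusted p was then 0.0773, and p53 targets were also lost without middle array 3, at up to 0.889. Hypoxia and glycolysis genes (median -0.10, camera adjusted p = 0.0194, or adjusted p = 0.653 with an estimated correlation) were also lost without middle array 1 or 3 or N-terminal array 2, at up to 0.194. Ribosomal protein genes (-0.07, 0.0175, or adjusted p = 0.77 with an estimated correlation, turning to 0.01 after quantile normalization) were also lost without middle array 2 or 3 or N-terminal array 3, at up to 0.344. Hypoxia and ribosomal genes lost it with no filter as well. The middle and N-terminal parts against untransduced cells correlated across genes with r = 0.567, against 0.5 simulated from shared controls alone.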

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

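The tests of lentiviral transduction and of shared untransduced arrays and the division of probe sets by gene symbols were chosen only after the result was seen, while the tests of scaling, of noise near the floor and of other splits of the arrays were planned.

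Signals also appeared among probe sets that stand for no single gene and were not used in the comparisons. Of the 5470 such probe sets above the filter, 46 were higher with full-length EZHIP and 91 with the C-terminal part than in untransduced cells, while 0 and 13 were lower and 0 changed with the middle or N-terminal part (limma). Of the 24909 probe sets of 1 gene, 409 and 774 were higher. The 4301 probe sets without a gene symbol held 37 and 62 of the rises and the 1169 with several symbols 9 and 29, and what they transcribe was not examined.

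The full-length protein and the C-terminal part differed in 6 gene lists by the camera test of their difference. The median difference, full-length minus C-terminal, was -0.681 for cancer-testis and germline genes, -0.453 for p53 targets, 0.168 for stress response genes, 0.165 for cholesterol synthesis, 0.15 for hypoxia and glycolysis and 0.111 for serum response genes. None of these held with an estimated correlation, where the smallest adjusted p was 0.0888. The dose of each protein was not measured, so a difference in the amount of protein and a difference in its activity remain untested explanations.

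The shared rise of 323 genes, such as IL13RA2 and FGF13, was weighed against technical explanations. Transduction itself predicts a like rise with the other constructs, but the median log2 fold change of these genes over the N-terminal and middle parts was 0.076 (upper quartile 0.293) against 1.49 with the full-length protein. Scaling between arrays is argued against as the whole cause by quantile normalization, which left 85.4% (276) of the 323 genes past the threshold in both comparisons. The larger pseudocount left 98.8% (319). It also shrinks the scatter of dim signals, and changed genes went from 354 to 370 and from 693 to 742. It therefore cannot decide on noise near the floor. With the stricter filter, which drops dim genes, 132 genes rose with the full-length protein and 263 with the C-terminal part, against 345 and 630. Shared untransduced arrays are argued against as the whole cause by the pair of comparisons without a shared array, in both of which 80.2% (259) of these genes were higher. A response to the C-terminal part of EZHIP may explain the rise, although culture differences shared by both groups (6 arrays at 6.26 to 6.94 mean log2, the other 9 at 4.80 to 5.03) and the unmeasured amount of the N-terminal and middle proteins stay open.

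Other splits of the arrays were counted for each comparison. With 3 arrays against 3 the 10 splits are too few for a share under 0.05. In the full-length comparison with untransduced cells 1 of 10 splits gave as many genes (354, highest other 0), and for the C-terminal part 1 of 10 (693, highest other 0). The N-terminal part gave 1 of 10 (1 gene, highest other 0), the middle part 10 of 10 (0 genes by limma, highest other 0), full-length against C-terminal part 10 of 10 (0 genes, highest other 0) and middle against N-terminal part 10 of 10 (0 genes, highest other 1). Against the pooled N-terminal and middle arrays, 1 of 84 splits gave as many genes for the full-length protein (959, highest other 527) and 1 of 84 for the C-terminal part (1714, highest other 583). These shares are under 0.05. They cover splits of these arrays only and do not exclude a difference between cultures, since the samples of a group may be technical.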

How the results depend on the processing

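Leaving out all arrays of number 1, and leaving out single arrays for the counts of lists, for the correlation and for the mean difference over the 323 genes, were chosen only after the data were seen. Of 279 named gene results past the threshold, 149 kept it under every alternative run on single genes that still tested the gene, and of 4320 alternative values 548 were weaker and 0 reversed. MAS5 signals near the floor limit the precision for genes such as EZHIP. Array weights, all probe sets, the variance trend, a fit of only the groups compared and the omission of all number 1 arrays were run on counts only. Except where fewer genes or arrays entered the test, the cause of the changes was not tested.

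Whether the numbers 1 to 3 mark shared cultures or days is not known. Not every same-number pair correlated over 0.1, so the main fit did not take the numbers as pairs. The arrays nevertheless shared structure by number, which the main fit left in the spread. The main counts, intervals and calls all come from that fit. Of 30 same-number pairs 19 correlated over 0.1 in their deviations from the group means (-0.222 to 0.433, median 0.153, against -0.081 for 60 other pairs), and 12 of 15 arrays lay nearest their own number. In all 5 groups the second principal component and the 18S signal were highest on array 1 and lowest on array 3. With a replicate block the genes changed by the C-terminal part came to 1119 (885 higher, 234 lower, against 630 and 63), those by the full-length protein to 493 (444 and 49, against 345 and 9), the lists of the middle part to 6, and EZHIP with the full-length protein to 1.675 (adjusted p = 0.0481).

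With a pseudocount of 1 EZHIP with the full-length protein was 2.795 (adjusted p = 0.145). With the pseudocount at the median of all values EZHIP with the full-length protein was 0.798 (adjusted p = 0.0245), and 1 gene differed between the full-length protein and the C-terminal part, as when only the groups compared entered the fit (1). With no filter 8 lists passed for the full-length protein against untransduced cells, 3 for the N-terminal part and 2 between middle and N-terminal parts, and the correlation of the full-length and C-terminal effects was 0.805. With the stricter filter 138 genes changed with the full-length protein and 306 with the C-terminal part, 433 and 934 against the mean of the N-terminal and middle parts. The lists were then 5 for the full-length protein against untransduced cells, and 7 and 8 for the full-length protein and the C-terminal part against the mean, with a correlation of 0.935 and 126 genes higher in both.

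After quantile normalization EZH2 and EED with the C-terminal part turned to 0.042 and 0.058, and 1 list passed for the middle part, 5 for the N-terminal part, 8 for the C-terminal part against the mean of both and 2 between the parts. Ribosomal genes turned to 0 with the N-terminal part, 0.009 with the C-terminal part against the mean and 0.011 between middle and N-terminal parts, housekeeping genes with the N-terminal part to -0.018 and mitosis genes with the C-terminal part against the mean to 0.034. With the mean of all probe sets of a gene, DNMT3A with the full-length protein turned to 0.204, EED with the C-terminal part to 0.181, RPS28 with the middle part to -0.048, RPS9 with the N-terminal part to -0.056 and TYMS, full-length against the mean, to 0.038, and 0 genes passed for the N-terminal part by limma. Array weights gave 737, 2283, 38 and 8 genes for the full-length, C-terminal, middle and N-terminal constructs against untransduced cells, 2 between full-length and C-terminal part, and 2066 and 3761 for these against the mean. Camera with an estimated correlation passed 0, 1, 0 and 0 lists for the 4 constructs against untransduced cells, 0 between full-length and C-terminal part, 0 and 1 for these against the mean, and 0 between middle and N-terminal parts. Without all arrays of number 1, 424 genes changed with the C-terminal part.

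Leaving out each array in turn gave 210 to 353 genes for the full-length protein, 388 to 668 for the C-terminal part, 471 to 1183 and 755 to 2176 for these against the mean, 198 to 325 higher in both, and a correlation of 0.866 to 0.911. The mean difference between full-length and C-terminal part over the 323 genes ranged from -0.439 to -0.166. Lists ranged from 6 to 15 for the C-terminal part, 1 to 5 for the middle part, 3 to 10 for the N-terminal part and 0 to 6 between middle and N-terminal parts. EZHIP ranged from 1.519 to 1.973 with the full-length protein (adjusted p from 0.0452 to 0.221), -0.131 to 0.624 with the C-terminal, -0.308 to 0.145 with the middle and -0.027 to 0.426 with the N-terminal part. With the C-terminal part EZH2 ranged from -0.074 to 0.032 and EED from -0.064 to 0.057. Between middle and N-terminal parts p53 targets ranged from -0.556 to -0.007, and serum response genes between full-length and C-terminal part from -0.013 to 0.312.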

Other observations

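The test of families of related X-linked genes was set only after a first value had been seen, and the excess of X-linked genes and the neighbouring pairs were noticed in these data before they were tested on them.

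Many of the 323 genes that rose with both the full-length protein and the C-terminal part lie on the X chromosome. The following genes were chosen after their values were seen. CAPN6, a calpain without protease activity, rose by 3.75 log2 units with the full-length protein and 4.43 with the C-terminal part, the teneurin TENM1, a synaptic adhesion protein, by 3.07 and 4.01, and the protocadherin PCDH19 by 1.77 and 2.3. NLGN4X, a neuroligin of synapses, rose by 2.43 and 3.76, and the serotonin receptor HTR2C by 2.16 and 2.78. Some risen genes were direct neighbours among the tested genes, as were the steroid-metabolising reductases AKR1C1, AKR1C2 and AKR1C3 on chromosome 10, the antiviral genes TRIM5 and TRIM6 on chromosome 11 and, beside them, the globin HBE1.

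Of 465 tested X-linked genes 54 (11.6%) rose with both constructs, against 269 of 12297 autosomal genes (2.2%). The odds ratio was 5.87 with a 95% interval of 4.23 to 8.04 (Fisher's exact test, two-sided, adjusted p = 5.58e-21). For rises against the mean of the N-terminal and middle parts it was 3.3 (2.52 to 4.27) with the full-length protein and 3.51 (2.81 to 4.37) with the C-terminal part. Single autosomes ranged from 0.12% (chromosome 19) to 5.85% (chromosome 18). The test and the intervals treat genes as independent, which neighbouring risen genes are not, so they overstate the precision. The filter also left out dim genes that did not rise, so the shares hold for tested genes only. Tested X-linked genes had no low starting level, with a median of 7.3 log2 units in untransduced cells against 6.24 to 7.61 on single autosomes. Stratified by the untransduced level the odds ratio was 6.16 (4.36 to 8.69). Dim genes that did not rise are missing from the strata, so this cannot test a larger pool of dim X-linked genes. With 1 gene kept per symbol root over all chromosomes, the median odds ratio was 5.23 over 1000 draws (3.31 to 7.62). The draws held a median of 195 X-linked genes. This argues against a few families of shared names as the whole cause. Related genes of different roots, such as MAGEB2 and MAGEC2, were not merged. The X chromosome may hold more silenced genes open to reactivation, which is a hypothesis that H3K27 methylation measured over these genes with and without EZHIP would test, and that was not tested here.

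The 323 genes also lay next to each other more often than shuffles within chromosomes gave, with 35 pairs of neighbouring tested genes against a mean of 13.5 and a maximum of 29 over 10000 shuffles (permutation p = 1e-04, the smallest these shuffles can give). Neighbours of the same symbol root are argued against as the whole cause, since 31 pairs were left without them (mean 12.8, maximum 27, permutation p = 1e-04). Sequences were not compared, so related genes of different names may remain among these pairs. The shuffles did not keep the starting level. In untransduced cells 51.1% of the 323 genes lay below the array median, against 9.4% of tested genes. The shuffles therefore cannot tell rises that follow regions from neighbours of like starting level, and the cause was not tested.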
